A study of Dendrobaena veneta with 18 samples.

How the data were processed

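RNA was measured by poly(A)-selected RNA sequencing on an Illumina instrument in the gut and the cerebral ganglion of adult earthworms of the species Dendrobaena veneta. The cerebral ganglion is the paired nerve mass above the pharynx that serves the worm as a brain. The worms lived for 28 days in topsoil with 0, 0.6 or 10 mg/kg of carbamazepine, an anticonvulsant drug that blocks voltage-gated sodium channels. Methanol was the solvent, and control soil received methanol alone. The labels list 18 samples, with 3 in each of the 6 combinations of tissue and dose. A column of values was present for 17 of them, and control gut replicate 1 was not analysed here because it has none. The labels do not say whether replicates are separate animals or pools, so all p-values measure only the spread between these samples.

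Per the labels, the reads were assembled de novo, that is without a reference genome. The gene identifiers have the form that the Trinity assembler writes. The submitters' processing notes name CASAVA and DESeq2. The versions of these tools, the counting program, the assembly filters and the annotation are not given in the sources used here. The authors deposited expected counts, which are estimated counts per assembled gene and are not scaled between libraries. The authors also deposited FPKM values, which are scaled to the length of the assembled gene and to the number of fragments in the library. Both tables hold 243619 assembled genes, called features here, and 63770 of them are 0 in all libraries. The identifiers group the features into 161562 components of the assembly. The files do not pair the identifiers with gene names, descriptions or positions. The lists of genes planned for drug metabolism, ion channels, neuropeptides, digestion, immunity and other functions could therefore not be run.

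The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 with limma 3.58.1 in R 4.3.3), which is two-sided. Expected counts were rounded to whole numbers and scaled with TMM factors. Features were kept by the package's own filter with its minimum count of 10 and minimum total of 15. Each fit had 1 coefficient per group and no other term. The Benjamini-Hochberg adjustment ran over all features kept, and a feature was called when its adjusted p was under 0.05. The doses were compared within each tissue, with the 3 groups of the tissue in 1 fit. The tissues, and the difference of each dose effect between tissues, were compared with all groups in 1 fit. These tests, the comparisons, most alternatives and the rule for naming features were fixed before the data were examined. Because the files give no gene names, the rule names per comparison at most the 2 called features of smallest adjusted p in each direction. Ties in adjusted p were ordered by p.

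The fits were planned on 9 gut libraries and 18 in all. They ran on 7 and 16 instead, because 1 library has no column and because gut low dose libraries 1 and 3 were averaged to 1 sample. That pair differed by little more than counting noise, as given with the libraries. The averaging was decided after the data were seen, and the design with both libraries separate is among the alternatives. Residual degrees of freedom were 4 for gut and 6 for the ganglion. The biological coefficient of variation was 64.1% in gut, 79.3% in the ganglion and 82.7% over both. Library totals ran from 12536754 to 18285270 counts. Where all libraries of a group were at 0, a fold is given as a lower bound against a floor of 3 counts per library. Where a group held 1 to 3 counts in all, the ratio is given with a 95% exact (Clopper-Pearson) counting interval. Floors and intervals cover counting error only. Values per feature are CPM values, that is counts relative to the TMM-scaled library total, and the standard error (SE) of a log2 fold is the fold divided by the square root of its F statistic.

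Libraries of 1 group were compared in pairs by the chi-square per feature, whose mean is 1 when counting noise alone separates them. Libraries were matched between tissues by 2741 features with at least 30 counts in a library and 0 in another, in each tissue. The match was the correlation of presence, at 5 counts or more, over these features, and pairs above 0.6 were taken as 1 worm. This matching was decided after the data were seen. Whether equal replicate numbers pair libraries within a tissue was checked by the correlation, across features, of their deviations from the group means. In the ganglion it was 0.185, 0.194 and 0.222 for the same-number pairs of control and high dose, which were therefore taken as paired by the values, not by the labels. The other same-number pairs lay between -0.00929 and 0.0952 in the ganglion and between -0.0359 and 0.0289 in gut.

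Sets of tissue-specific features were defined from the data as those with at least 20 CPM in every library of 1 tissue and at least 20 times the highest value in the other. They were defined in a dose group that the comparison did not use. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, and adjusted over 12 tests. These sets were chosen after the data were seen. The overlap of calls of both doses was compared with 20 simulations in which the doses have no effect and share their controls.

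The alternatives were DESeq2 1.42.0 (Wald test), DESeq2's scaling factors in edgeR (RLE), no filter on low counts, a fit with only the groups compared, an absolute log2 fold of at least 1, the replicate number as a block, limma on FPKM with pseudocounts of 1 and 0.1 and without a filter, and leaving out each library. Added after the data were seen were the gut low dose pair as separate samples, gut high dose libraries 1 and 3 averaged as well, counts summed per assembly component, and the matched worm as a block. Tables were prepared and drawn in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

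The main test was tested on simulated data with the spread of these libraries. With no change simulated, edgeR called 0 features in either tissue, DESeq2 called 162 in gut and 139 in the ganglion, and edgeR without the filter called 142 and 30. The share of edgeR features at an unadjusted p under 0.05 was then 4.61% in gut and 4.52% in the ganglion. Each tissue had a single such data set, of independent libraries without transcripts that single worms carry or lack. The 0 calls therefore do not give the rate of false calls in the real data. With changes simulated, edgeR made 2 false calls in gut and 1 in the ganglion. Of simulated 4-fold changes, edgeR called 2.17% in gut and 0% in the ganglion. Of 16-fold changes it called 12.8% and 27.1%, and of 256-fold changes 52.4% and 57.1%. DESeq2 called 15.2% and 11.1% of the 4-fold changes. A low number of calls by the main test therefore does not exclude changes below those sizes.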

Results

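The data are counts of assembled genes, called features, in 8 gut and 9 cerebral ganglion libraries of Dendrobaena veneta. The gut groups hold 2 control, 3 low dose (0.6 mg/kg carbamazepine) and 3 high dose (10 mg/kg) libraries, and each ganglion group holds 3. Library totals ran from 12536754 to 18285270 counts, with a median of 13640404. A library had between 69387 and 92447 features with at least 1 count. Tissue was the main axis of the data, since the first principal component carried 52.0% of the variance and the second 10.3%. The files give no names for the features, so features are given by identifier (without its TRINITY prefix), and no gene list or function could be assigned to them.

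Several libraries came close to one another within and between tissues. Gut low dose libraries 1 and 3 differed with a mean chi-square of 2.32 per feature, and 5 features had at least 50 counts in 1 of them and 0 in the other. This mean was 2.27 for features with 20 to 100 counts and 2.37 for those with 1000 to 10000. Gut high dose libraries 1 and 3 had 9 such on/off features, with a mean chi-square of 2.56 at 20 to 100 counts and 41.5 at 1000 to 10000. The other 14 pairs within a group had 381 to 1443 on/off features and means of 117 to 484 at 1000 to 10000 counts. Between tissues, 8 pairs of a gut and a ganglion library matched in which features were present, with correlations across features of at least 0.677, and all 8 pairs were of the same dose group. Of all 136 pairs of libraries, 10 lay above 0.6 and 3 between 0.2 and 0.6. By these matches the 17 libraries came from 9 worms, 6 of them with gut libraries. Only 3 of the 8 matched pairs carried the same replicate number. Ganglion control 2, ganglion low dose 3 and ganglion high dose 3 had no gut partner.

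**Figure D1:**
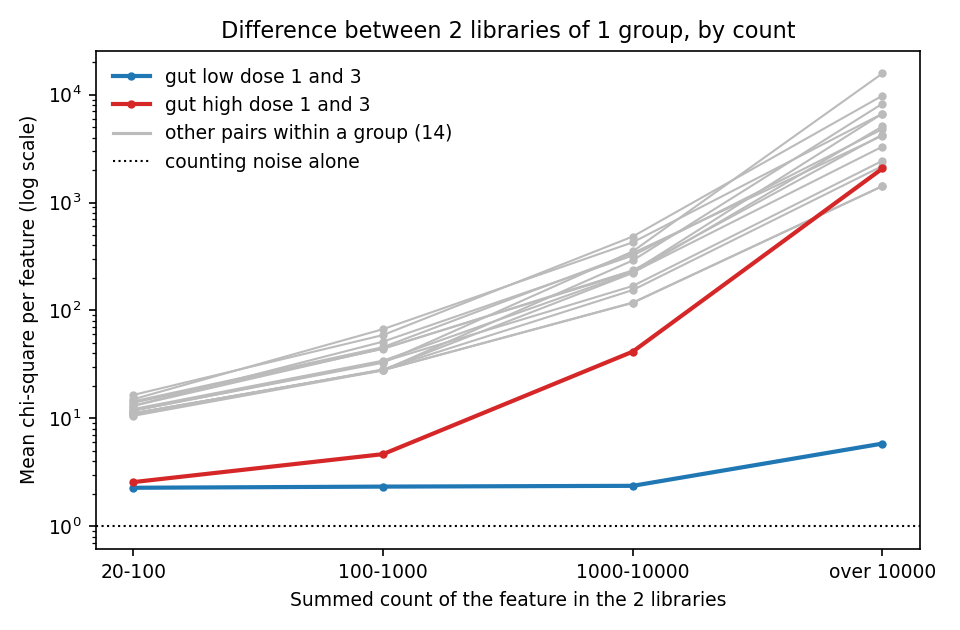
Mean chi-square per feature between libraries of 1 group (vertical, log scale, 1 is counting noise alone) by the summed count of the feature (horizontal), 1 line per pair. Gut low dose 1 and 3 stay near 2.3 up to 10000 counts, gut high dose 1 and 3 reach 41.5 at 1000 to 10000, and the 14 other pairs lie at 117 to 484 there.

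Gut and cerebral ganglion of control worms differed in 13890 features, the most of any comparison made here. Of these, 6785 were higher in the ganglion and 7105 higher in gut. DN86895_c0_g2 stood at 76.5 ± 26.1 CPM (SD, n = 3) in the control ganglion and 0.299 ± 0.111 (n = 2) in control gut. DN106278_c1_g2 stood at 37.0 ± 10.95 and 0.913 ± 0.0442 CPM. On the gut side, DN74933_c1_g1 reached 836 ± 143 CPM in control gut, against 2 counts in all 3 control ganglia, a ratio of 16713 (95% counting interval 4626 to 138014). DN100436_c0_g2 reached 1771 ± 336 CPM in control gut and 2.21 ± 0.443 in the control ganglion. Fitted differences of at least 4-fold were found for 5734 features on the ganglion side and 6310 on the gut side.

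The tissue comparison tested 69685 features with edgeR's quasi-likelihood test. The log2 fold of ganglion over gut was 7.98 (SE 0.60, adjusted p = 2.5e-05) for DN86895_c0_g2 and 5.33 (SE 0.47, adjusted p = 4.7e-05) for DN106278_c1_g2. It was -13.89 (SE 0.81, adjusted p = 1.0e-05) for DN74933_c1_g1 and -9.64 (SE 0.63, adjusted p = 1.8e-05) for DN100436_c0_g2. These 4 features kept their calls in all 64 of the alternative fits, with adjusted p up to 0.00693. DESeq2 called 19358 features, 13545 of them by both tools, with 10079 higher in the ganglion and 9279 in gut, so which tissue held more calls depended on the tool. The tissue difference held in exposed worms for most of these features. With libraries of 1 worm averaged, leaving 2 gut and 3 ganglion samples per dose, the tissues did not overlap, in the control direction, for 11327 of the 13890 at the low dose (81.5%) and for 12616 at the high dose (90.8%), where chance gives 10%. The opposite direction without overlap was seen for 129 and 5. The count depends on the small control gut group, since it was 6380 without gut control 2 and 6008 without gut control 3. It was 9088 with only the control groups in the fit.

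At the low dose, 12 gut features differed from control, 6 higher and 6 lower. DN89951_c4_g1 and DN102191_c1_g2 had 0 counts in both control guts and stood at 19.9 ± 2.80 and 13.8 ± 2.24 CPM (n = 2) in low dose gut, at least 81.0-fold and 55.9-fold higher. DN69829_c0_g1 and DN76289_c6_g3 went the other way. They stood at 56.8 ± 2.44 and 38.6 ± 5.54 CPM in control gut (n = 2) and at 0 in low dose gut, at least 318-fold and 216-fold lower. DN88869_c4_g1, named by the rule for the comparison of doses, rose from 3.58 ± 0.0502 to 103.5 ± 1.84 CPM (n = 2 and 2).

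All 4 features named here for gut at the low dose had an adjusted p of 0.0237 by edgeR's quasi-likelihood test, over 50068 features. The log2 fold of DN88869_c4_g1 was 4.85 (SE 0.34, adjusted p = 0.0237). At an unadjusted p under 0.05 there were 3942 features, where 5% of those tested is 2503.4, and DESeq2 called 766 (342 higher, 424 lower). The balance turned with limma on FPKM, which called 182 higher and 80 lower with a pseudocount of 1. All 4 are among the features that matched the libraries to worms, so the ganglia of matched worms resemble the guts in them by construction. DN69829_c0_g1 had 1 and 0 counts in ganglion low dose 1 and 2, whose worms match the low dose guts, and 1147 in ganglion low dose 3. It had 473, 8 and 1229 counts in ganglion control 1, 2 and 3, of which replicate 2 has no gut partner. DN102191_c1_g2 had 0 counts in ganglion control 1 and 3 and 146 in ganglion control 2. Leaving out any 1 of the 4 samples compared, gut control 2, gut control 3, gut low dose 2 or the averaged low dose pair, edgeR called 0 features, and so it did with the high dose pair averaged as well. The log2 fold of DN89951_c4_g1 stayed between 10.9 and 11.2 without these samples, and its adjusted p between 0.0623 and 0.133.

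**Figure D2:**
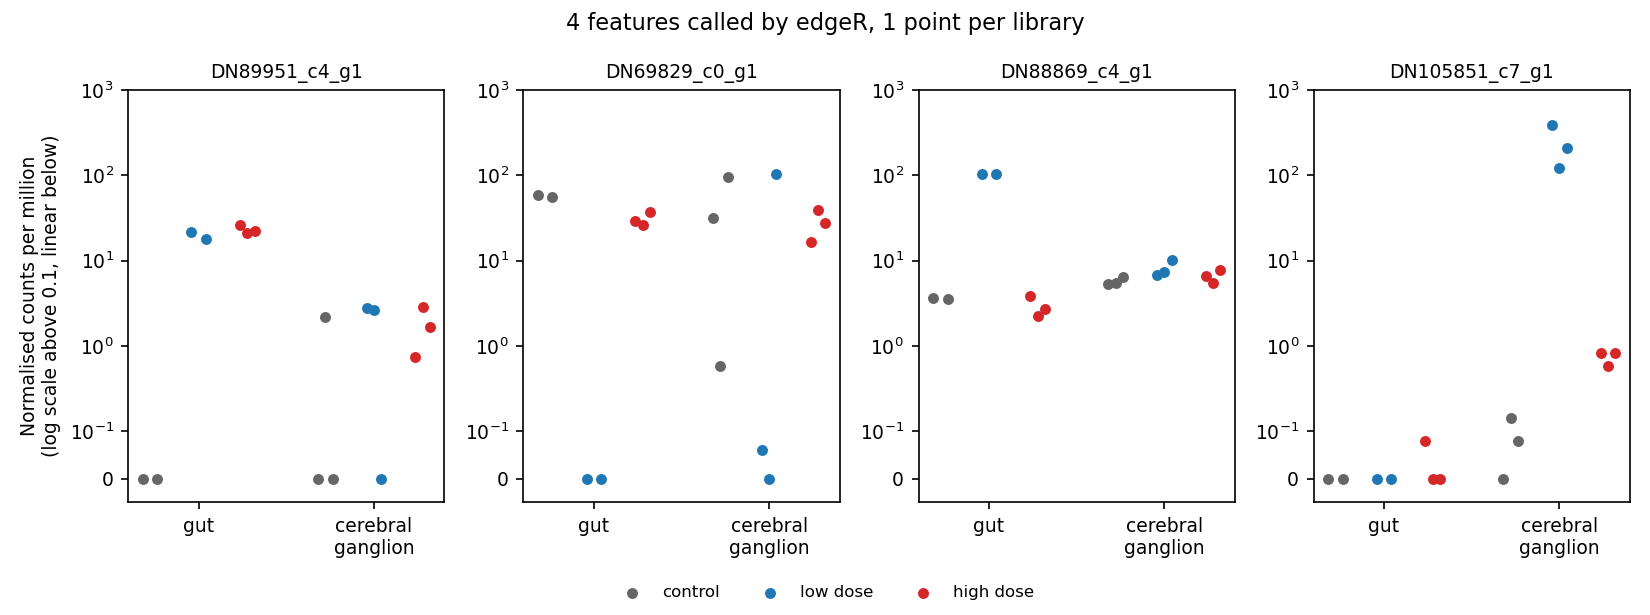
Normalised counts (CPM) of 4 called features (vertical, log scale above 0.1 and linear below) in gut and cerebral ganglion, 1 point per library, with gut low dose 1 and 3 as 1 averaged point, in control (grey), low dose (blue) and high dose (red). DN69829_c0_g1 is at 0 in both low dose gut points and near 0 in ganglion low dose 1 and 2, and DN105851_c7_g1 exceeds 1 CPM only in low dose ganglia.

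Features specific to gut took a smaller share of the counts in low dose gut. In a set of 499 such features defined in high dose worms, 439 were lower and 60 higher in low dose than in control gut, with a median log2 fold of -1.11 against 0.04 for all features tested. They held 41.9% ± 5.73 (SD, n = 2) of the counts in control gut, 25.3% ± 1.09 (n = 2) in low dose gut and 41.3% ± 10.9 (n = 3) in high dose gut. The high dose libraries defined the set, so their share is high partly by construction. The set test (camera, limma) gave an adjusted p of 1.9e-33 at the preset correlation and an adjusted p = 0.166 with an estimated correlation. With fry the adjusted p was 0.140. Of 170 ganglion-specific features from the same worms, 126 were higher in low dose gut, with a median log2 fold of 0.50. Their adjusted p was 0.00363 by camera (limma), and the adjusted p = 0.558 with an estimated correlation.

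**Figure D3:**
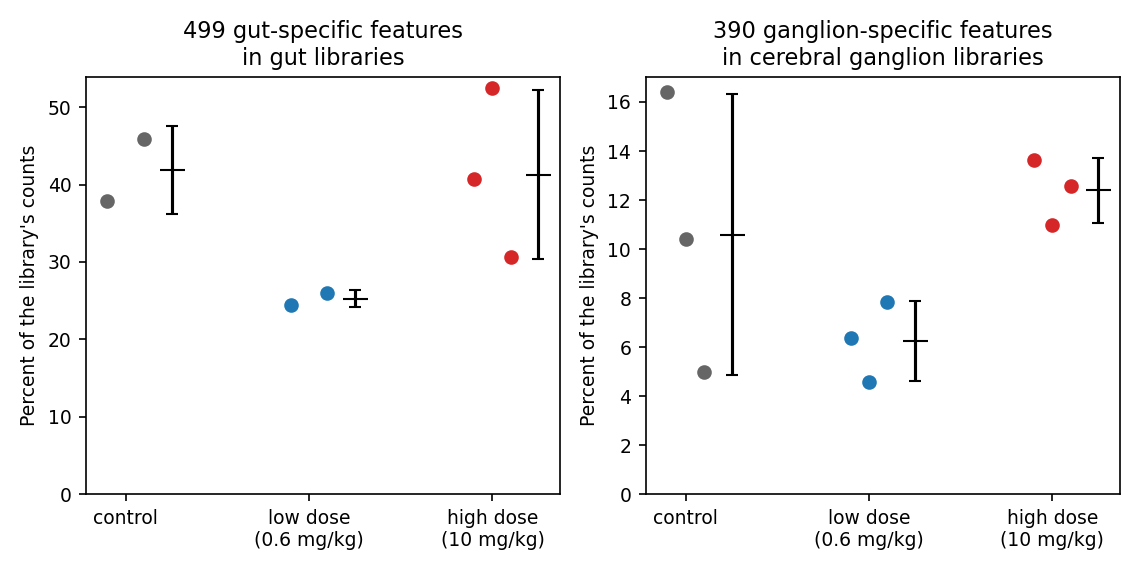
Percent of each library's counts in 499 gut-specific features in gut (left) and in 390 ganglion-specific features in the cerebral ganglion (right), by dose. Points are libraries and bars are the mean ± SD. Low dose gut sits at 24.5% to 26.0%, below the control guts at 37.9% and 46.0%. The high dose guts, at 30.7% to 52.4%, come from 2 worms by the matches. High dose libraries defined both sets, so their points are high partly by construction.

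At the high dose, 3 gut features differed from control, and all 3 were higher. By the matches the 3 high dose gut libraries came from 2 worms. DN89951_c4_g1 stood at 22.99 ± 2.60 CPM (n = 3) and DN102191_c1_g2 at 15.8 ± 1.57, at least 93.4-fold and 64.2-fold above the control guts at 0 counts. DN87472_c3_g2, chosen after its values were seen to complete the 3, rose from 0.399 to 11.6 CPM, a log2 fold of 4.83. The same 3 were called in the same direction at the low dose.

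The adjusted p was 0.0470 for all 3 features by edgeR's quasi-likelihood test. At an unadjusted p under 0.05 there were 3884 of 50068 features, and DESeq2 called 860 (529 higher, 331 lower). With limma on FPKM and a pseudocount of 1 the balance turned, to 50 higher and 86 lower. Without any 1 of gut control 2, gut control 3, gut high dose 1, gut high dose 2 or gut high dose 3, edgeR called 0. Averaging gut high dose 1 and 3, which matched as 1 worm, also gave 0. The median log2 fold of 675 gut-specific features defined in low dose worms was -0.06, with an adjusted p of 0.0102 by camera (limma) and an adjusted p = 0.241 with an estimated correlation. Of 100 ganglion-specific features 72 were higher in high dose gut, with a median log2 fold of 0.77, an adjusted p of 0.0213 by camera (limma) and 0.544 with an estimated correlation.

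Between the doses, 11 gut features differed in the main fit, 8 higher and 3 lower at the high dose. By the matches the 3 high dose libraries came from 2 worms, and no feature was called when libraries of 1 worm were averaged. DN69829_c0_g1 stood at 30.8 ± 5.48 CPM (n = 3) and DN76289_c6_g3 at 51.1 ± 12.6 in high dose gut, at least 173-fold and 286-fold above low dose gut at 0 counts. DN88869_c4_g1 fell from 103.5 ± 1.84 CPM (n = 2) at the low dose to 2.94 ± 0.842 (n = 3) at the high dose, below its control mean of 3.58. DN90884_c1_g3 fell from 41.7 ± 2.95 to 5.75 ± 0.900 CPM. In control gut DN69829_c0_g1 stood at 56.8, DN76289_c6_g3 at 38.6 and DN90884_c1_g3 at 9.75 CPM.

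In the test between doses the adjusted p was 0.0245 for DN69829_c0_g1 and 0.0298 for DN76289_c6_g3 by edgeR's quasi-likelihood test. The log2 fold of high over low dose was -5.14 (SE 0.29, adjusted p = 0.0245) for DN88869_c4_g1 and -2.86 (SE 0.23, adjusted p = 0.0452) for DN90884_c1_g3. The last call was lost with RLE scaling, where the adjusted p was 0.0502, within a range over its alternatives up to 0.407. DESeq2 called 1250 features (720 higher, 530 lower), and edgeR had 4626 at an unadjusted p under 0.05. On FPKM limma called more lower than higher, with 71 higher and 271 lower at a pseudocount of 1, and so did edgeR with the low dose pair as separate samples, with 70 and 96. Without gut low dose 2, the averaged low dose pair, gut high dose 1 or gut high dose 3, edgeR called 0. It also called 0 with gut high dose 1 and 3, which matched as 1 worm, averaged to 1 sample. A set of 839 gut-specific features defined in control worms had a median log2 fold of 0.72, with 692 higher at the high dose. Its adjusted p was 2.6e-17 by camera (limma), and the adjusted p = 0.193 with an estimated correlation.

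Taken over both doses, 8 gut features differed from control, 3 higher and 5 lower. DN89951_c4_g1 and DN102191_c1_g2 rose, with adjusted p of 0.0320 and 0.0336 by edgeR's quasi-likelihood test. DN69829_c0_g1 fell, with a log2 fold of -6.76 (SE 0.31, adjusted p = 0.0320), and so did DN86603_c2_g3, from 15.2 CPM in control gut to 0 at the low dose and 6.66 at the high dose (adjusted p = 0.0478). The lower calls rest on low dose gut, where 4 of the 5 were at 0 and DN97773_c4_g2 was near 0. At the high dose DN76289_c6_g3 stood above control, at 51.1 against 38.6 CPM, and DN89454_c7_g1, chosen after its values were seen, at 19.4 against 24.2. The fitted folds of features at 0 in a group depend on the prior count and are no bounds. DESeq2 called 615 features, and edgeR had 3717 at an unadjusted p under 0.05. The count was 23 without gut high dose 2, 1 without gut control 2, and 0 without gut control 3, the averaged low dose pair, gut low dose 2, gut high dose 1 or gut high dose 3. Without gut high dose 2, the high dose group is 2 libraries of 1 worm by the matches, so that fit counts 1 animal 2 times. With gut high dose 1 and 3 averaged as 1 worm the count was 0. With RLE scaling it was 5, of which 3 were higher and 2 lower.

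Both doses share their gut controls, so some overlap arises without an effect. The 3 features called at both doses, all higher, compare with 0 in the simulations and with 3.6e-04 expected from independent lists in that direction and 0 in the other. With no change simulated edgeR called 0 gut features, so the simulated 0 gives no expectation for lists of 12 and 3 calls. With gut high dose 1 and 3 averaged, 0 features were called at both doses. The covariance of the log2 folds of both doses across features was 1.61, against 0.912 ± 0.0186 (SD over 20 simulations) from shared controls alone. Their correlation across features was 0.442, below the simulated 0.567 ± 0.00597. With gut high dose 1 and 3 averaged as 1 worm, the covariance was 1.56 against 0.929 ± 0.0154 and the correlation 0.468 against 0.510 ± 0.00438. The controls are too few to be split between the doses, so part of the excess could not be separated from the shared controls. By DESeq2, 159 features were higher and 68 lower at both doses, against means of 27.1 and 7.80 and maxima of 41 and 14 in 20 simulations with shared controls. In the opposite directions there were 2, against a maximum of 1. The simulated lists held means of 142.7 and 135.75 calls, against 766 and 860 in the data, so the shared numbers are not directly comparable. The simulations also hold no transcripts that single worms carry or lack, so the excess does not show a dose effect.

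In the cerebral ganglion, 1 feature differed between low dose and control. DN105851_c7_g1 stood at 238 ± 135 CPM (SD, n = 3) in low dose ganglia, between 120.9 and 385.7, against 0.0741 ± 0.0719 (n = 3) in control ganglia. In high dose ganglia it stood at 0.748 ± 0.147 CPM (n = 3), between 0.579 and 0.835, far below the low dose but above the control range of 0 to 0.144. It had no more than 1 count in any gut library of any group. Across the 3 libraries of each group the counts were 10333 and 3, a ratio of 3522 (95% counting interval 1205 to 17083).

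The log2 fold of DN105851_c7_g1 was 11.51 (SE 0.89, adjusted p = 0.0169) by edgeR's quasi-likelihood test, over 48132 features, and DESeq2 gave an adjusted p of 4.0e-26. Over its 14 alternatives the call was kept in 10, and the adjusted p ran up to 0.168, the value without ganglion control 3. The call was also lost with the replicate number as a block and with only the groups compared in the fit. Differences below the adjusted threshold were widespread. At an unadjusted p under 0.05 there were 8060 features, with 4898 higher and 3162 lower. That is 3.35 times 2406.6, which is 5% of those tested. Features are not independent, so a count above 5% can arise without a dose effect. Other splits of the same 6 libraries gave 1595 to 3830. DESeq2 called 4017 features, 2971 higher and 1046 lower. The number called by edgeR was 175 without ganglion low dose 3, 3 without ganglion low dose 2, 2 without ganglion control 1, and 0 without ganglion control 2 or without ganglion control 3. The number at an unadjusted p under 0.05 stayed between 6435 and 9335 when any 1 of these 6 libraries was left out.

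The mean share of counts in features specific to the ganglion was smaller in low dose than in control ganglia, but the ranges overlapped. Of 390 such features defined in high dose worms, 352 were lower at the low dose than in control, with a median log2 fold of -0.94 against -0.03 for all features. They held 10.6% ± 5.72 (SD, n = 3) of the counts in control ganglia, 6.26% ± 1.63 in low dose ganglia and 12.4% ± 1.34 in high dose ganglia, whose libraries defined the set. Control ganglia ranged from 4.97% to 16.4%, which spans the low dose range of 4.58% to 7.83% but for its lower end. The set test (camera, limma) gave an adjusted p of 9.6e-13 at the preset correlation and an adjusted p = 0.416 with an estimated correlation. The 499 gut-specific features from the same worms held 0.0320% ± 0.00825 (n = 3) of the counts in control and 0.0859% ± 0.0530 (n = 3) in low dose ganglia. Of the 95 of them tested, 53 were higher, with a median log2 fold of 0.36 and an adjusted p of 0.126 by camera (limma). Adjusted over the list alone 9 were called, 8 higher and 1 lower, and over all features 0.

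**Figure D4:**
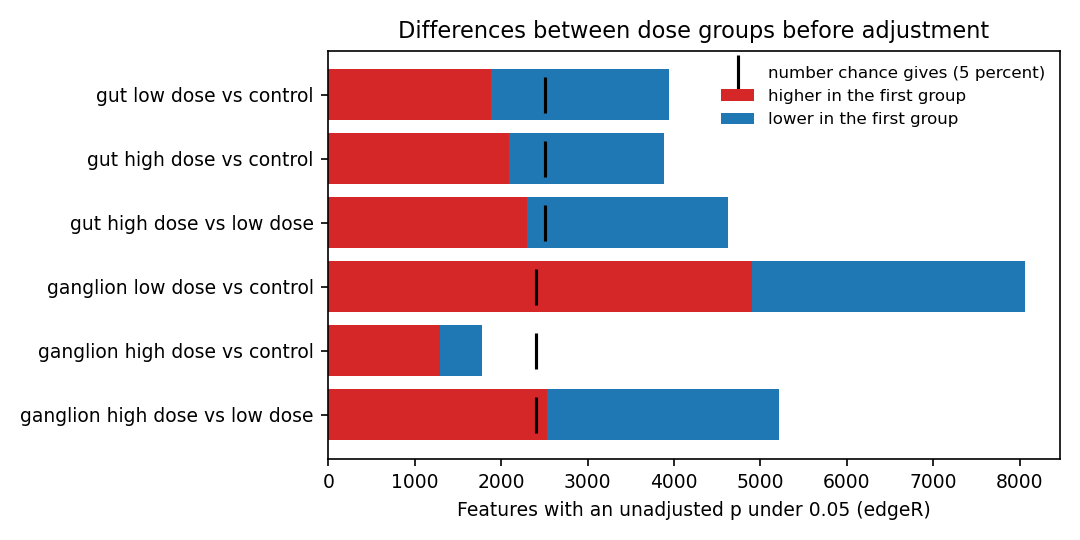
Number of features at an unadjusted p under 0.05 by edgeR (horizontal) in each comparison of dose groups, higher (red) and lower (blue) in the group named first. The black line, labelled as the number chance gives, is 5% of the features tested. Features are not independent, so numbers above it can arise without a dose effect. Ganglion low dose against control has the longest bar at 8060, and ganglion high dose against control lies below the black line at 1780.

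At the high dose, no ganglion feature passed the test against control. By edgeR's quasi-likelihood test 0 features were called, with a smallest adjusted p of 0.608. At an unadjusted p under 0.05 there were 1780, which is 0.740 times 5% of the features tested. DESeq2 called 156 features, 132 higher and 24 lower. Ganglion high dose 3 shared features with ganglion control 3, since the 2 correlated at 0.477 in the features that matched the libraries. Of 42 features private to that control, 40 were present in high dose 3 at a median of 0.251 of their level. Of 53 private to high dose 3, 10 were present in that control. The sharing thus ran mostly 1 way, and its source was not tested. Without ganglion high dose 3 edgeR called 0, with 2011 features at an unadjusted p under 0.05, and without ganglion control 3 it called 0, with 2062. The number at an unadjusted p under 0.05 was 2856 without ganglion control 2, again with 0 calls. The ganglion-specific features defined in low dose worms had a median log2 fold of 1.60, with 417 of 451 higher. They held 3.53%, 8.86% and 13.0% of the counts in the control ganglia and 10.7% to 11.9% in high dose ganglia, within the control range. Their adjusted p was 4.0e-25 by camera (limma) at the preset correlation, and the adjusted p = 0.241 with an estimated correlation. Of the 129 gut-specific features 66 were higher and 63 lower, with a median log2 fold of 0.04 and an adjusted p of 0.0933 by camera (limma). With the replicate number as a block it was 0.0413, and 0.483 when the correlation was estimated.

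Between the doses a set of ganglion-specific features passed the set test at the preset correlation and not with an estimated one. Of its 222 features, defined in control worms, 210 were higher at the high than at the low dose, with a median log2 fold of 1.10. Camera (limma) gave an adjusted p of 4.7e-37, and the adjusted p = 0.166 with an estimated correlation. Fry gave an adjusted p of 0.140 for 1 direction and 0.0325 for changes in either direction. The 222 gut-specific features in the same ganglia had a median log2 fold of -1.26, with an adjusted p of 1.3e-05 by camera (limma) and an adjusted p = 0.416 with an estimated correlation. By single features, edgeR's quasi-likelihood test called 0, with a smallest adjusted p of 0.0693, while 5211 were at an unadjusted p under 0.05 and DESeq2 called 1395. Without ganglion low dose 2 edgeR called 2.

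Over both doses against control, edgeR's quasi-likelihood test called 0 ganglion features, with a smallest adjusted p of 0.241. The number at an unadjusted p under 0.05 was 4784, and DESeq2 called 1506, of which 1288 were higher. No ganglion feature was called at both doses by edgeR, in the data or in the simulations with shared controls. By DESeq2, 100 were higher and 9 lower at both doses, against means of 18.65 and 4.30 and maxima of 28 and 8 in the simulations. In the opposite directions there was 1, as in the highest simulation. The simulated lists held means of 125.55 and 113.65 calls, against 4017 and 156 in the data, so the shared numbers are not directly comparable. The covariance of the log2 folds was 1.53, against 0.733 ± 0.0120 (SD over 20 simulations), and their correlation across features was 0.596 against 0.499. As in gut, the simulations hold no transcripts that single worms carry or lack. They also hold none of the features that ganglion control 3 and high dose 3 share, so the excess does not show a dose effect.

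The effect of the low dose differed between tissues for 1 feature. DN88869_c4_g1 rose in gut from 3.67 ± 0.113 to 106 ± 2.95 CPM (n = 2 and 2), while in the ganglion it stood at 5.57 ± 0.517 in control and 7.85 ± 1.81 at the low dose (n = 3 and 3). The difference of the log2 folds, ganglion minus gut, was -4.36 (SE 0.48, adjusted p = 0.0266) by edgeR's quasi-likelihood test. At an unadjusted p under 0.05 there were 5585 of 69685 features, and DESeq2 called 1312. The number called was 0 without gut control 2, gut control 3, the averaged low dose pair, gut low dose 2, ganglion control 2 or ganglion low dose 2. It was 2 without ganglion control 1 or ganglion control 3, 3 without ganglion low dose 1 and 6 without ganglion low dose 3. RLE scaling gave 3, of which 2 were higher and 1 lower. Counts summed per assembly component gave 1 call in the opposite direction, higher in the ganglion minus gut difference. With the matched worm as a block, which uses that gut and ganglion libraries came from the same worms, it was 96, 87 higher and 9 lower, and DN88869_c4_g1 kept its call (adjusted p = 0.0378, edgeR).

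The test of the high dose effect between tissues called 1 feature, whose low counts in the ganglion leave its response there unknown. DN86038_c0_g2 had 10300 and 18027 counts in the control guts, 10, 17 and 9 in the low dose guts and 0 in all 3 high dose guts. In the ganglion it had between 0 and 7 counts in control, where a fall like that in gut could not be seen, and between 3 and 26 at the high dose. The adjusted p was 0.0128 by edgeR's quasi-likelihood test. In gut alone the feature was called in no comparison of doses by this test. DESeq2 called 89 features, and edgeR had 1620 at an unadjusted p under 0.05. The call was lost without gut high dose 1, gut high dose 2, gut high dose 3, ganglion control 2, ganglion control 3, ganglion high dose 2 or ganglion high dose 3, each of which left 0 features called. Averaging gut high dose 1 and 3 also left 0, and the matched worm as a block gave 2. In the control guts its counts lay within 2% of those of DN97773_c4_g2, a feature chosen after its values were seen.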

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

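The tests of the repeated libraries, of a wrong dose label, of gut tissue in the ganglia, of the splits by pair and of the directions outside the matching features were chosen after the results were seen. The tests of worm-specific transcripts, depth and the other splits of libraries were set before theirs.

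A pair of features passed the test of a difference between the 2 tissues in the response to a dose. DN88869_c4_g1 rose by more at the low dose in gut than in the ganglion (adjusted p = 0.0266, edgeR). In the ganglion alone its log2 fold was 0.50 (SE 0.38, adjusted p = 0.564, edgeR), with all 3 low dose values above the control values. DN86038_c0_g2 was abundant in control gut, at 9 to 17 counts in low dose gut and at 0 in high dose gut (adjusted p = 0.0128, edgeR). In the ganglion alone its log2 fold at the high dose was 1.93 (SE 1.14, adjusted p = 1, edgeR). In gut alone edgeR called it in no comparison of doses. With 0 to 7 counts in control ganglia its counts could not fall there as they did in gut. This call therefore does not show that the tissues respond differently, and no explanation for the lower counts in exposed gut was tested.

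Some libraries that carry different replicate numbers resemble repeats of 1 worm. For gut low dose 1 and 3, the noise at 1000 to 10000 counts was 1.04 times that at 20 to 100 counts, which is consistent with 1 worm or library measured 2 times, with noise about 2.3 times that of counting. For gut high dose 1 and 3 the same ratio was 16.2, which argues against 1 library sequenced 2 times, while their 9 on/off features are consistent with 2 libraries of 1 worm. Of the 8 gut libraries, 0 matched a ganglion of another dose group best, which argues against a dose label that is wrong in 1 tissue of these worms. A label wrong for a whole worm stays open, and so does that of the 3 ganglia without a gut partner, of which high dose 3 correlated at 0.477 with ganglion control 3 and 0.403 with gut control 3. How the worms were dissected or pooled stays open, and no biological explanation was tested.

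Many gut differences between the low dose and control may be transcripts that single worms carry or lack in all tissues. Among 2042 features at an unadjusted p under 0.05 and an absolute log2 fold of at least 1 for the low dose, the median log2 difference in the gut direction was 0.66 in ganglia of the same worms and -0.12 in ganglia of other worms, a difference of 0.78 (95% bootstrap interval 0.65 to 0.89 over features, which are not independent), and 63.4% against 44.5% kept the direction. For 1890 features of the high dose it was 1.12 and -0.08, a difference of 1.20 (1.11 to 1.30), and 86.5% against 45.1% kept the direction. Outside the features that matched the libraries, the differences were 0.52 and 0.98, with 57.6% against 44.7% and 84.1% against 47.2% keeping the direction. The other worms add only 1 ganglion per group, low dose 3, high dose 3 and control 2, so the intervals do not cover the spread between worms. The explanation stays open for the high dose, since high dose 3 correlated at 0.477 with ganglion control 3. Both its label and the source of the features it shares with that control are open. The label of low dose 3 is open too, though its highest correlation with a library of another dose was 0.176. A dose effect on part of the features stays open at both doses, since each gut group holds 2 worms.

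The broad difference of low dose ganglia, with 8060 features at an unadjusted p under 0.05, is hard to place. Depth is argued against, since the number was 3.38 times that expected after all ganglion libraries were thinned to 12536754 counts, and so is gut tissue in the dissection. Gut-specific features reached at most 0.572% of their low dose gut level in the set from high dose worms and 1.94% in the set from control worms, both in ganglion low dose 2. Of the 4898 higher features 4156 had counts in low dose gut, and 99.8% of these rose by more than 1.94% of their gut level. For the 477 features that ganglion low dose 1 and 2 hold and the other ganglia lack, leaving them out tests nothing, since the filter kept 0 of them, and whether their source also shifted other features stays open. Of the 10 splits of the 6 libraries, 1 gave as many, the highest other split gave 3830, and 10 splits are too few for a share under 0.05. In 4670 features all 3 low dose ganglia lay outside the range of the other 6 libraries, which 1 of 84 ways to take 3 libraries reached (highest other 3194). That is the smallest share 84 ways can give, and it argues against chance only if the libraries are exchangeable. Ganglion low dose 1 and 2 share the 477 features, and ganglion control 3 and high dose 3 correlated at 0.477, so chance was not excluded. The dose, a shared batch or the dissection of other tissue stay open.

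Other splits of the ganglion libraries gave these numbers of calls by edgeR. For low dose against control, 1 of 10 splits gave at least the real count of 1 and the highest other gave 0. For the other 3 comparisons the real count was 0, so every split, 10 of 10 for high dose against control, 10 of 10 for high against low dose and 84 of 84 for either dose against control, gives at least as many, and these counts decide nothing about chance. The highest other splits gave 233, 0 and 4. That with 233 had control 1, control 3 and high dose 1 on 1 side, which points to a structure of the samples. The replicate numbers were taken to pair these 6 libraries, from correlations of 0.185, 0.194 and 0.222 and not from the labels. Among the other 3 splits that part all 3 pairs, as the real one does, the highest gave 0, while that with 233 parts 1 pair. This rests on a weak pairing and on few splits, so it decides nothing about chance. The sets of 10 splits are too few for a share under 0.05.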

How the results depend on the processing

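The separate low dose pair, the averaged high dose pair, the component sums, the worm block and the block in the set tests were chosen after the data were seen. Numbers of calls are given in the order low dose against control, high dose against control, high against low dose and either dose against control, first for gut and then for the ganglion, followed by the tissue difference of the low and of the high dose effect, and by the calls shared by both doses in gut and ganglion. The main numbers were 12, 3, 11 and 8, then 1, 0, 0 and 0, then 1 and 1, then 3 and 0. Where these moved, the cause was not tested, except that the fits with fewer samples have fewer degrees of freedom.

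DESeq2 gave 766, 860, 1250 and 615, then 4017, 156, 1395 and 1506, then 1312 and 89, then 227 and 109. No filter on low counts gave 3363, 3228, 4198 and 3423, then 7128, 1755, 4621 and 4115, then 2058 and 607, then 1168 and 1257, and with no change simulated this setting also called features. FPKM with a pseudocount of 1 gave 262, 136, 342 and 108, then 108, 5, 59 and 9, then 261 and 76, then 75 and 1. FPKM with a pseudocount of 0.1 gave 154, 186, 229 and 125, then 58, 6, 26 and 11, then 129 and 59, then 73 and 4. FPKM with a pseudocount of 1 and no filter gave 20, 19, 26 and 19, then 16, 1, 5 and 9, then 1145 and 191, then 9 and 1.

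With only the groups compared in the fit, gut gave 0 for low dose, high dose and high against low dose, ganglion low dose gave 0 and high against low dose 1, both tissue differences and the shared gut calls gave 0, and control ganglion against control gut gave 9088 in place of 13890. With the replicate block, fitted with the low dose pair as separate samples, all 4 gut comparisons, the shared gut calls and ganglion low dose gave 0, and the tissue difference of the low dose effect gave 5. In gut 1 of 8 libraries resembled its own number best, and in the ganglion 8 of 9 did. Deviations from a group mean cancel within the group, so these correlations are tied together and the counts are weak evidence about pairing. The highest, 0.222, joins ganglion control 3 and high dose 3, which share other features too. In ganglion high dose against control, where the libraries were taken as paired by number, the block moved the adjusted p of the gut-specific set by camera (limma) from 0.0933 to 0.0413 and changed no other call. RLE factors gave 5 for either dose in gut (3 higher, 2 lower), 3 for the tissue difference of the low dose effect, and 8 for high against low dose in gut (7 higher, 1 lower, against 8 and 3).

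The low dose pair as separate samples gave 46, 49, 166 and 42 in gut, 8 for the tissue difference of the low dose effect and 19 shared gut calls. The high dose pair averaged as well gave 0, 0, 0 and 0 in gut, 0 for the tissue difference of the high dose effect and 0 shared gut calls. Counts summed per component gave 4, 14 and 6 for the first 3 gut comparisons, 2 for high against low dose in the ganglion, 0 for the tissue difference of the high dose effect and 1 shared gut call. The worm block gave 96 and 2 for the tissue differences. The balance of directions turned in some settings. On FPKM with pseudocounts of 1 and 0.1 it was 182 higher to 80 lower and 103 to 51 for low dose in gut (DESeq2 342 to 424), and 71 to 271 and 82 to 147 for high against low dose (DESeq2 720 to 530, low dose pair separate 70 to 96). For high dose in gut it was 50 to 86 and 100 to 86 (DESeq2 529 to 331). The component sums gave 1 higher and 0 lower for the tissue difference of the low dose effect, against 0 and 1.

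Leaving out 1 library gave 0 to 0 for low dose and 0 to 0 for high dose in gut, 0 to 11 for high against low dose, and 0 to 23 for either dose. In the ganglion it gave 0 to 175 for low dose, 0 to 0 for high dose, 0 to 2 for high against low dose and 0 to 0 for either dose. The tissue comparison ranged from 6008 to 11978, and the tissue differences from 0 to 6 and from 0 to 1. The 11 and the 23 in gut came without gut high dose 2, where the high dose group is 2 libraries of 1 worm by the matches. A group left with 1 library was assumed to vary like the others. Of the features named for dose comparisons, 137 of 271 alternative fits kept the call, 134 lost it and 0 turned direction, and those named for the tissue comparison kept it in 64 of 64. Tissue-specific sets that passed at the preset correlation all missed the threshold with an estimated correlation. At these depths edgeR called 12.8% of simulated 16-fold changes in gut, and thinning all ganglion libraries to the smallest total gave 7933 features at an unadjusted p under 0.05 for the low dose, against 8060.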

Other observations

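The values here come from comparisons chosen after the data were seen, except the principal components of the ganglion, which were planned.

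On the first principal component, low dose worms lay apart from both other groups in both tissues. On the first principal component of the ganglion libraries (32.2% of the variance) the low dose libraries lay at 122.6 to 190 and the other 6 at -159 to 22.9. On that of the gut samples, with libraries of 1 worm averaged (34.4%), they lay at -127 and -103 and the others at -25.9 to 138. By the matches each gut sample came from a worm that also gave a ganglion library. The 2 low dose guts came from the worms of ganglion low dose 1 and 2, so the tissues are not independent of each other. The gut part rests on 2 low dose worms, and gut control 2, at -25.9, lay nearer to them than to gut control 3, at 117. Of the features outside the range of the other ganglia in all low dose ganglia, 2851 were above it and 1819 below. For the control ganglia such features numbered 1463.

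The 15 features called in any gut comparison of doses were followed through the 6 worms with both tissues. A gut group was at 0 for 9 of them. Since 9 of the 15 are among the features that matched the libraries to worms, their agreement between gut and ganglion is built in. Of the other 6, DN88869_c4_g1 ran from 28 to 1794.5 counts in gut and from 79 to 114 in the ganglion, and DN97182_c4_g3, chosen after its values were seen, from 49 to 2720.5 and from 38 to 165. In DN87472_c3_g2 the ganglion followed the gut. It had 6 and 4 gut counts and 14 and 21 ganglion counts in control worms, against 131 to 195.5 and 282 to 659 in exposed worms. DN90884_c1_g3 had 696.5 and 705 counts in low dose guts and 289 and 160 in their ganglia, against 75 to 129 and 56 to 121 elsewhere. DN84716_c1_g1 had at most 7 counts in these ganglia, and DN97773_c4_g2 is given below.

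DN97773_c4_g2, chosen after its values were seen, was abundant in most libraries and nearly missing in the worms of the low dose guts. It had 10301 and 18138 counts in the control guts, 3, 0 and 2 in low dose gut and 7981 to 10836 in high dose gut. In the ganglia it had 23351 to 148703 counts in control, 242, 313 and 83449 at the low dose and 28527 to 52049 at the high dose.

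A group of 477 features was present in ganglion low dose 1 and 2 and nearly absent from the other ganglia. Together they held 1630 CPM in ganglion low dose 1 and 6719 in ganglion low dose 2. In the gut libraries they held 200 to 375 CPM, with 36 to 66 of the 477 at 5 counts or more. Of 42 features found in ganglion control 3 but no other ganglion outside high dose 3, 40 (95.2%) were present in ganglion high dose 3, at a median of 0.251 of their level. In the reverse direction it was 10 of 53 (18.9%).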
